A study of Mus musculus with 3 samples.

How the data were processed

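Droplet-based single-cell RNA-seq was done on cells of mouse patellar tendon, sorted to leave out blood-lineage and endothelial cells, per the labels' protocols. There were 3 libraries: 1 of mice aged 2 weeks and 2 of mice aged 20 weeks. The counts are UMI counts per gene and barcode, which the authors made with Cell Ranger 6.1.2 on the mm10 build, per the file headers and the submitters' processing notes. The annotation release and the count settings are not stated. The deposited matrices are not normalized, the libraries are not pooled, and the barcodes deposited start at 500 UMIs. The feature list held 32288 entries, of which 3 are added transgene sequences (EGFP, tdTomato and tdTomato-WPRE). The 78 features whose symbol is shared with another feature were kept apart by their identifiers. Of 32285 Ensembl identifiers, 32158 (99.61%) were found in GENCODE's mouse annotation of GRCm38, the assembly that mm10 names, and 31436 of these carried the same symbol. Positions are given 1-based from that annotation. Genes with near-identical copies, such as the haemoglobin chains and Ly6a with Ly6c1, were not told apart beyond what the authors' counting did.

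Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 4964, 609 and 1015 barcodes of the 2-week library, 20-week replicate 1 and 20-week replicate 2. Doublets were called in each library with the score that the scrublet method defines, at an expected rate of 0.8% per 1000 barcodes, and left out. The score was rewritten with exact neighbours so that it could be rebuilt exactly, and scrublet's own program was not run. They were 39, 3 and 1 barcodes, or 0.786%, 0.493% and 0.0985% against 4.52%, 0.572% and 0.935% expected from loading, so the call rate of the 2-week library was well under its expected rate. The files do not say whether the barcodes are all cells of each library, so class shares, cell totals and expected doublet rates hold for the barcodes given. Counts per cell were scaled to a fixed total and log-transformed. Clustering used 2000 variable genes, chosen in scanpy 1.11.5 with the library as batch, without the genes of the cell cycle, dissociation and sex-linked lists and without mitochondrial, ribosomal, haemoglobin and transgene features. Each gene was z-scored within each library. A graph of 15 neighbours on 30 principal components, weighted by shared neighbours, was split by the Leiden method on modularity at resolution 0.5 with seed 0 (python-igraph 0.11.9). Clusters were named from markers of 15 cell types fixed before the data were examined. A cluster took a name when at least 2 markers of that type were among its 10 leading genes by fold over the other cells of the same library and at least 3 markers were detected. Leading genes were ranked by that fold, taken within each library that held at least 20 cells of the cluster and averaged over these, from CPM with 10 CPM added and among genes with at least 20 CPM. This naming rule, the way the graph was built and the exclusion of haemoglobin genes from the ranking were set after marker genes of clusters had been seen. Clusterings from 2 earlier runs of the same settings were also looked at, class sizes moved between them, and the first result that could be rebuilt exactly was kept. No gene test was run on the earlier clusterings. Nearly all progenitor-like cells came from different clusters at the 2 ages, and tenocyte-like cells in part, so the clusters are named beside the values.

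UMI counts were summed per library over all cells, over tenocyte-like cells and over progenitor-like cells, with at least 20 cells per library required. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization and filterByExpr on the age group, with the Benjamini-Hochberg threshold at 0.05. With 1 library against 2 there is 1 residual degree of freedom, and the lone 2-week library is assumed to vary like the 20-week libraries. The median log2 fold change over all genes was 0.04 in all cells, 0.05 in tenocyte-like and 0.02 in progenitor-like cells. The adjusted p-values named without a tool are from this test for genes and from limma's camera (3.58.1) for gene lists. DESeq2 1.42.0 was the alternative tool, and an adjusted p that it did not give was left out of counts of lost calls. CPM values in the text are scaled by TMM for single genes in a class and are plain CPM for sums over other cell types' genes and for transgenes. Log2 ratios of single 20-week libraries over the 2-week library, used where a replicate was left out, have a prior count of 2 and no test. The interaction of class and age was fitted with the library as a block. A fold against a group at 0 was taken as a bound with 3 counts over the group in place of 0. Where a group had 1 to 3 counts, the ratio of the summed counts is given with its exact 95% binomial interval, called the counting interval. These intervals and bounds cover counting error only.

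There were 19 test lists and 8 lists of other cells' RNA, fixed before the data were examined. The test lists were tendon lineage, fibrillar collagens and collagen processing, leucine-rich proteoglycans and mature matrix, elastic fibre, matrix degradation, progenitor markers, antioxidant enzymes, NRF2 targets, sources of reactive oxygen, oxidative phosphorylation, cell cycle, senescence and secretory factors, complement, interferon response and antigen presentation, imprinted growth network, secretory pathway and unfolded protein response, dissociation and heat shock, fibrocartilage, and adipogenic. The lists of other cells were immune, endothelial, erythroid, skeletal muscle fibre, mural, Schwann, keratinocyte and sex-linked genes. Lists share genes with the cell markers: the fibrocartilage list holds all 8 chondrocyte markers, and the leucine-rich list holds 4 of the 8 tenocyte markers. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, and with their median set among 10000 random lists matched on mean expression. Named genes were chosen by a rule fixed before the data were examined. In each class they were the 10 with the largest fitted change in each direction among called genes changed at least 2-fold the same way in both 20-week libraries, with a mean of at least 50 CPM and without unnamed, mitochondrial and ribosomal genes. To these came the 3 members of each list with the smallest p, 16 genes always reported, and up to 5 genes per direction of the interaction. Other members of lists that the text names are called members of that list.

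Each library's shares of cells are given with an exact (Clopper-Pearson) 95% interval. For shares of cells with a UMI, each cell was thinned without replacement to 2000 UMIs and shallower cells were left out. The scripts for the gene and list tests were tested on simulated counts with 200 changed genes, after the tests on the real counts had been run. In each simulation these genes all changed by the same fold, and all genes had a common spread. At a true fold of 16, edgeR recovered 92.5% of these in all cells, 72% in tenocyte-like and 96.5% in progenitor-like cells, with 5, 4 and 7 false calls. At a fold of 4 it recovered 3.5%, 0% and 28%. DESeq2 recovered 86%, 55% and 70% at 16-fold and 10%, 7.5% and 21.5% at 4-fold. Alternatives were DESeq2, RLE scaling, no filter on low counts, sums thinned to the smallest library, stricter cell filters of at least 1000 genes and at most 5% mitochondrial UMIs, doublets kept, resolution 1.0, z-scoring over all cells, a prior count of 0.5, thinning to 1000 UMIs and each 20-week library left out. Clustering each library on its own was added after seeing the data. The checks of sex-linked, B-lineage and transgene UMIs in single cells were also chosen after seeing the data. The marker genes, barcodes and matrices of all 3 libraries were used, and no sample was left out.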

Results

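Cells of the mouse patellar tendon that were neither of the blood lineage nor endothelial were isolated by flow sorting after digestion with collagenase. Their messenger RNA was counted cell by cell with a droplet method that attaches a unique molecular identifier (UMI) to each captured molecule. The animals were labelled wild type. There was 1 library from mice aged 2 weeks and there were 2 from mice aged 20 weeks, called 20-week replicate 1 and 20-week replicate 2. The labels do not say how many animals went into a library, so p-values of the gene tests here measure only the spread between these libraries. Those of the gene lists set a list's genes against the other genes. The 2-week library held 5654 barcodes and 35556626 UMIs, 20-week replicate 1 held 715 barcodes and 1886785 UMIs, and replicate 2 held 1169 barcodes and 5849867 UMIs. After the cell filters and the removal of called doublets, 4925, 606 and 1014 cells were used, with 34198171, 1784768 and 5571741 UMIs. Barcodes past the filters had median totals of 6570, 2848 and 5132 UMIs and median counts of 2213, 1121 and 1885 genes, in the same order. The 20-week libraries differed from each other well beyond counting error, with a chi-square per degree of freedom of 32.3 over 11699 genes.

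Tenocyte-like cells, named from markers of the mature tendon fibroblast such as Tnmd, Scx and Fmod, made up 13.6% of the 2-week cells (exact 95% interval 12.7 to 14.6), 39.8% of 20-week replicate 1 (35.8 to 43.8) and 11.1% of replicate 2 (9.27 to 13.2). Progenitor-like cells, named from markers such as Cd55, Cd248 and Pi16, made up 18.0% (16.9 to 19.1), 25.6% (22.1 to 29.2) and 53.7% (50.6 to 56.9). Mural-like cells, the contractile cells of vessel walls, made up 13.7%, 7.26% and 4.04%, and myogenic-like cells 2.42%, 1.16% and 3.06%. Schwann-like cells made up 0.690%, 0.330% and 0.197%. Chondrocyte-like cells made up 10.5% of the 2-week library and 0.165% of replicate 1, and none of the 1014 cells of replicate 2, which allows up to 0.296%. Osteogenic-like cells made up 3.09% at 2 weeks and were 0 of 606 and 0 of 1014 cells at 20 weeks, which allows up to 0.495% and 0.296%. Ibsp and Spp1, leading genes of the osteogenic-like cluster, also led cluster 18, an unnamed one of 46 cells of replicate 2. These limits therefore hold for the name and not for the cell type. Muscle fibre-like cells made up 0.284% at 2 weeks, 0 of 606 cells in replicate 1 and 8.28% of replicate 2. The remaining 37.7%, 25.7% and 19.5% of cells fell in clusters without a name. These shares are descriptions of 3 sorted libraries and cover counting error only. Progenitor-like cells of the 2 ages came nearly all from different clusters and tenocyte-like cells in part, and no comparison of class sizes between ages was drawn. The progenitor-like share also moved with the clustering, to 16.7%, 21.3% and 22.9% at resolution 1.0 and to 18.4%, 4.77% and 0.827% with stricter cell filters. With these filters an unnamed cluster, led by Ccl7, Tnfaip6 and Ifi205, held 18, 166 and 518 cells of the 3 libraries. The low 20-week shares there thus also describe which clusters took the name. Of the tenocyte-like clusters, number 5 held 445, 8 and 6 cells of the 3 libraries in the order above, number 6 held 213, 6 and 74, and number 9 held 14, 227 and 33. Number 9 had the tenocyte markers Comp and Scx among its 10 leading genes, and neither Tnmd nor Fmod. Of the progenitor-like clusters, number 1 held 18, 149 and 542 cells, number 2 held 679, 6 and 3, and number 12 held 188, 0 and 0.

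The first comparison asked which genes differed between the ages in the whole sorted population, from the UMI sums over all cells of each library. Galnt15, of the family of enzymes that start mucin-type O-glycosylation, rose from 0.403 at 2 weeks in UMIs scaled to a library total of 1000000 (CPM) to 136 and 114 CPM at 20 weeks, a log2 fold change of 8.24 (SE 0.71, adjusted p = 0.0293). Cthrc1, a secreted protein linked to collagen matrix, fell from 398 to 5.16 and 5.06 CPM (log2 -6.28, SE 0.54, adjusted p = 0.0293). Igf2, the imprinted fetal growth factor, fell from 1158 to 21.3 and 15.5 CPM (log2 -5.99, SE 0.63, adjusted p = 0.0447). Fbn2, the fibrillin of fetal microfibrils, had 1891 UMIs at 2 weeks and 2 at 20 weeks, a ratio of 214 (counting interval 59.3 to 1772). Among the cartilage genes, Snorc was at least 216-fold lower at 20 weeks, Cnmd was lower by a ratio of 347 (62.2 to 13720.0), and Col11a2 had a log2 change of -4.74. Snorc, Cnmd, Col11a2 and Igf2 are each a leading gene of a cluster made up mostly of 2-week cells, so these values also describe which clusters each library filled. Across 13311 genes tested, 2 were higher and 14 lower at 20 weeks by edgeR's quasi-likelihood test, with 1102 at an unadjusted p under 0.05. Col1a1, the main collagen of tendon, stood at 24263 CPM at 2 weeks and 1325 and 930 at 20 weeks, without passing this test (log2 -4.43, SE 0.89, adjusted p = 0.227).

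The test in all cells was not stable. DESeq2 called 115 genes higher and 76 lower, 15 of the 16 above among them, and returned no adjusted p for 1291 genes. With the sums thinned to the smallest library, or with stricter cell filters, edgeR called 0 genes, with 797 and 955 genes at an unadjusted p under 0.05.

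Gene lists fixed before the data were examined moved in both directions in all cells, by limma's camera test with a preset correlation of 0.01 between genes. Complement (adjusted p = 6.0e-11), interferon response and antigen presentation (2.9e-10), sources of reactive oxygen (7.7e-06), leucine-rich proteoglycans and mature matrix (1.8e-04), NRF2 targets (0.00328), senescence and secretory factors (0.0046) and the dissociation and heat shock list (0.0129) shifted up. The imprinted growth network (1.6e-25), fibrocartilage (6.2e-20), fibrillar collagens and collagen processing (5.6e-12), cell cycle (0.00119), elastic fibre (0.00483) and tendon lineage (0.0096) lists shifted down. The fibrocartilage list holds all 8 chondrocyte markers, and chondrocyte-like cells were 10.5% and 0.165% of the first 2 libraries and 0 of 1014 cells in replicate 2. Its shift thus also describes which clusters each library filled, and it was not tested without these cells. None of these 13 kept its call with an estimated correlation, where the adjusted p was 0.671 for tendon lineage and senescence, 0.686 for cell cycle and 0.589 for the others. That alternative has 1 residual degree of freedom, so the lost calls were nearly fixed by the design and say little about a list. Against random lists matched on expression, tendon lineage (adjusted p = 0.409) and elastic fibre (0.0897) did not pass. Few single members passed the test over all genes: 5 of the 14 measured fibrocartilage genes, Fbn2 in the elastic fibre list and Igf2 in the imprinted list fell. Adjusted over the list alone, 12 of 16 imprinted genes fell, 6 of 31 collagen genes fell, and 7 of 13 complement genes rose while 1 fell. Matrix degradation (adjusted p = 0.0646), oxidative phosphorylation (0.0693), the secretory pathway and unfolded protein response (0.265), progenitor markers (0.389), antioxidant enzymes (0.756) and the adipogenic list (0.838) did not pass. The antioxidant list had a test direction of up, a mean log2 change of 0.34 and a median of -0.12, and the adipogenic list had a direction of up, a median of 0.08 and a mean of -0.41.

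The comparison within tenocyte-like cells asked how the matrix-building cells of the tendon differed between 2 and 20 weeks. Type I collagen RNA was far lower at 20 weeks: Col1a1 fell from 87916 CPM to 1664 in replicate 1 and 2843 in replicate 2 (log2 -5.29, SE 1.19, adjusted p = 0.00166), and Col1a2 fell from 60494 to 2620 and 3319 (log2 -4.35, SE 1.13, adjusted p = 0.00953). Within cluster 6 alone, the one cluster of the class with at least 20 cells of both ages, the log2 ratio of Col1a1 in replicate 2 was -2.68, against -4.95 in the class. The imprinted growth genes went the same way, with Igf2 at 189 CPM at 2 weeks and 1.49 and 12.1 at 20 weeks (log2 -4.90, SE 0.75, adjusted p = 1.0e-06) and H19 at 787 UMIs at 2 weeks and 0 in both 20-week libraries, at least 56.2-fold lower. Gpx3, a secreted glutathione peroxidase, rose from 2.94 CPM to 3465 and 1435 (log2 9.68, SE 1.62, adjusted p = 7.1e-06). C3, the central component of complement, rose from 1.10 CPM to 228 and 199 (log2 7.53, SE 1.07). The class held 672, 241 and 113 cells with 5956310, 726187 and 418905 UMIs. Of 8017 genes tested, 167 were higher and 148 lower at 20 weeks, with 931 at an unadjusted p under 0.05. The spread shared across genes entered this test with 94.5 prior degrees of freedom, against 16.3 in progenitor-like cells and 5.54 in all cells. These calls therefore rest mostly on that shared spread and little on each gene's own. Most 2-week cells of this class lay in clusters 5 and 6 and most of replicate 2 in cluster 6. Most cells of replicate 1 lay in cluster 9, which took its name from Comp and Scx. With each library clustered on its own, an alternative chosen after seeing the data, 288 genes were called, 236 of them the same genes in the same direction. DESeq2 called 138 genes, of which 120 were also called above, and other settings gave between 188 and 674. Without a test, 474 genes were at least 2-fold higher and 556 at least 2-fold lower in both 20-week libraries, and 139 changed 2-fold in opposite directions. Data simulated with these libraries' spread gave 648 to 677 unchanged genes past 2-fold the same way in both.

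In tenocyte-like cells the collagen list shifted down as a whole (adjusted p = 7.6e-11; adjusted p = 0.693 with an estimated correlation), with 8 of 29 measured members lower and 1 higher over all genes, and 13 lower and 1 higher adjusted over the list alone. Besides type I collagen, Col14a1, Loxl2, Crtap, P3h1 and Serpinh1, the collagen chaperone, fell by 2.20 to 2.92 on the log2 scale, and Col11a1 fell by 3.48. By DESeq2 the adjusted p of Col14a1 was 0.0987. P4ha2, a subunit of the prolyl hydroxylase that modifies collagen, was the member that rose (log2 2.51, SE 0.69, adjusted p = 0.0175). Col3a1 stood at 2060 CPM at 2 weeks and 920 and 1094 at 20 weeks and did not pass (log2 -1.03, SE 0.92, adjusted p = 0.876). The elastic fibre list did not pass as a whole (adjusted p = 0.177), with 3 of 15 members lower and 2 higher over all genes, and 5 lower and 3 higher adjusted over the list alone. Fbn2 had 698 UMIs at 2 weeks and 2 at 20 weeks, a ratio of 74.8 (20.6 to 619), and the microfibril genes Mfap2 and Mfap4 fell (log2 -3.98 and -3.84). The leucine-rich proteoglycan and mature matrix list shifted up (adjusted p = 2.3e-05; adjusted p = 0.693 with an estimated correlation), with 3 of 21 members higher and 1 lower over all genes, and 10 higher and 1 lower adjusted over the list alone. Prelp, a proteoglycan that anchors collagen to other matrix, rose from 42.1 CPM to 2975 and 1348 (log2 5.68, SE 1.32, adjusted p = 0.00236), and Tnxb, tenascin-X, rose by a log2 change of 3.13 (SE 0.96, adjusted p = 0.0400). Fmod, the fibromodulin of collagen fibrils, stood at 4203 CPM at 2 weeks and 3876 and 5126 at 20 weeks (log2 0.10, SE 1.04, adjusted p = 0.997). Matrix degradation genes did not move as a list (adjusted p = 0.797), with a test direction of down, a median log2 change of -0.09 and a mean of 0.06.

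The tendon lineage list shifted down in tenocyte-like cells (adjusted p = 0.0200; adjusted p = 0.693 with an estimated correlation), with 3 of 17 members lower over all genes, and 5 lower and 2 higher adjusted over the list alone. All 8 markers that named the class are in this list, which did not pass against random lists (adjusted p = 0.201). Tnmd, the tendon membrane protein tenomodulin, was at 8897 CPM at 2 weeks and 133 and 1259 at 20 weeks (log2 -3.68, SE 1.04, adjusted p = 0.0195), and the log2 ratio was -6.06 in replicate 1 and -2.82 in replicate 2. Kera, the proteoglycan keratocan, was at 1778 CPM at 2 weeks and 148 and 143 at 20 weeks. Tnmd and Kera lead clusters 6 and 5, so their values also describe which clusters each library filled. Scx, the transcription factor scleraxis, stood at 1632, 2583 and 983 CPM and did not pass (log2 0.13, SE 0.98, adjusted p = 0.996). Npy, Cytl1 and Clu, which lead cluster 9, stood at 0, 2.57 and 331 CPM at 2 weeks, at 1353, 1714 and 15488 in replicate 1 and at 12.1, 26.2 and 1310 in replicate 2. Slurp1 went from 0 CPM to 955 and 24.2, at least 1014-fold higher over the group, and Ibsp had 2 UMIs at 2 weeks and 626 and 25 at 20 weeks, a ratio of 1519 (419 to 12571). Ibsp also leads cluster 15, which was osteogenic-like, lay outside this class and was made up of 152 2-week cells alone. Its value here thus also describes which cells the class took in at each age. Ibsp, Cytl1, Clu, Slurp1 and Npy are also leading genes of cluster 18, 46 cells of replicate 2 that lay outside the class. At resolution 1.0 a cluster of 72 cells of replicate 2, led by Ibsp, Clu and Cytl1, was tenocyte-like. The values of these genes in replicate 2 thus also describe which of its cells took the name. For Npy, Cytl1 and Slurp1 the adjusted p of DESeq2 was 0.140, 0.18 and 0.0747. The fibrocartilage list did not pass (adjusted p = 0.675), with 3 of 10 members higher and 2 lower over all genes and over the list alone, a test direction of down, a median of -0.09 and a mean of 1.38.

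Of 4 redox lists in tenocyte-like cells, 2 shifted and 2 did not pass. The antioxidant enzyme list did not shift as a whole (adjusted p = 0.927), with 3 of 23 members higher and 2 lower over all genes, and 4 higher and 2 lower adjusted over the list alone. Besides Gpx3, Sod3, the extracellular superoxide dismutase, rose from 47.2 CPM to 829 and 214 (log2 3.47, SE 1.02, adjusted p = 0.0281), and Mt2, a metal-binding metallothionein, rose from 53.1 to 2012 and 776 (log2 4.71, SE 1.20, adjusted p = 0.00771). Without replicate 1 the log2 change was 2.16 for Sod3 and 3.85 for Mt2, and without replicate 2 it was 4.11 and 5.22. Gpx7 and Gpx8, peroxidases of the endoplasmic reticulum, fell (log2 -2.89, SE 0.66 and -2.37, SE 0.72). The sources of reactive oxygen shifted up (adjusted p = 3.4e-04; adjusted p = 0.693 with an estimated correlation and 0.201 with sums thinned to the smallest library), with 2 of 5 measured members higher over all genes and over the list alone. They were Nox4, an NADPH oxidase, which rose from 6.24 CPM to 52.2 and 74.6 (log2 3.33, SE 0.71, adjusted p = 8.0e-04), and Maob, a mitochondrial monoamine oxidase, with 2 UMIs at 2 weeks, 16 in replicate 1 and 8 in replicate 2 (ratio 56.0, interval 13.9 to 489). NRF2 targets did not pass (adjusted p = 0.107; 0.0148, upward, with sums thinned to the smallest library): Gstm1, a glutathione transferase, rose (log2 4.42, SE 0.88), Slc7a11, the cystine transporter, had 155 UMIs at 2 weeks and 0 at 20 weeks, at least 11.1-fold lower, and these were the 2 of 17 members called over all genes and over the list alone. The adjusted p of Slc7a11 was 0.119 by DESeq2, and with each library clustered on its own it was 0.144 for Slc7a11 and 0.574 for Maob. Nfe2l2, which encodes NRF2 itself, stood at 17.6, 47.7 and 90.7 CPM (log2 1.96, SE 0.67, adjusted p = 0.0934). The oxidative phosphorylation list shifted down (adjusted p = 0.00196; adjusted p = 0.922 with an estimated correlation) with 0 of 38 members called either way over all genes or over the list alone, at a median log2 change of -0.68.

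Complement was the list with the lowest adjusted p among those that rose in tenocyte-like cells (2.4e-11; adjusted p = 0.693 with an estimated correlation), with 6 of 10 measured members higher over all genes and 9 adjusted over the list alone. Next to C3, the proteases C1s1 and C1ra rose by log2 changes of 4.36 and 4.27, and C4b had 2 UMIs at 2 weeks and 14 and 30 at 20 weeks (ratio 103, interval 26.8 to 874). The interferon list shifted up (adjusted p = 6.8e-04; adjusted p = 0.752 with an estimated correlation and 0.0784 with sums thinned to the smallest library), with no member of 14 called over all genes and 1 adjusted over the list alone. The progenitor marker list also shifted up (adjusted p = 0.00478; adjusted p = 0.752 with an estimated correlation), with 4 of 14 members higher over all genes, and 7 higher and 1 lower adjusted over the list alone. Ly6a, the stem cell antigen Sca-1, rose from 19.6 CPM to 316 and 220 (log2 3.77, SE 0.90, adjusted p = 0.00348), and Ly6c1 rose from 13 to 485 and 179 (log2 4.67, SE 1.00). The imprinted growth network shifted down (adjusted p = 6.1e-13; adjusted p = 0.693 with an estimated correlation), with 7 of 15 members lower over all genes and 10 adjusted over the list alone. Dlk1, a growth regulator of the fetus, was at least 19.1-fold lower, and Mest had 969 UMIs at 2 weeks and 3 at 20 weeks, a ratio of 69.2 (23.6 to 336). The cell cycle (adjusted p = 0.556), senescence (0.927), secretory pathway (0.107), dissociation (0.927) and adipogenic (0.330) lists did not pass. Cdkn1a, the p21 cell cycle inhibitor, stood at 113, 1207 and 133 CPM (adjusted p = 0.196).

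**Figure D1:**
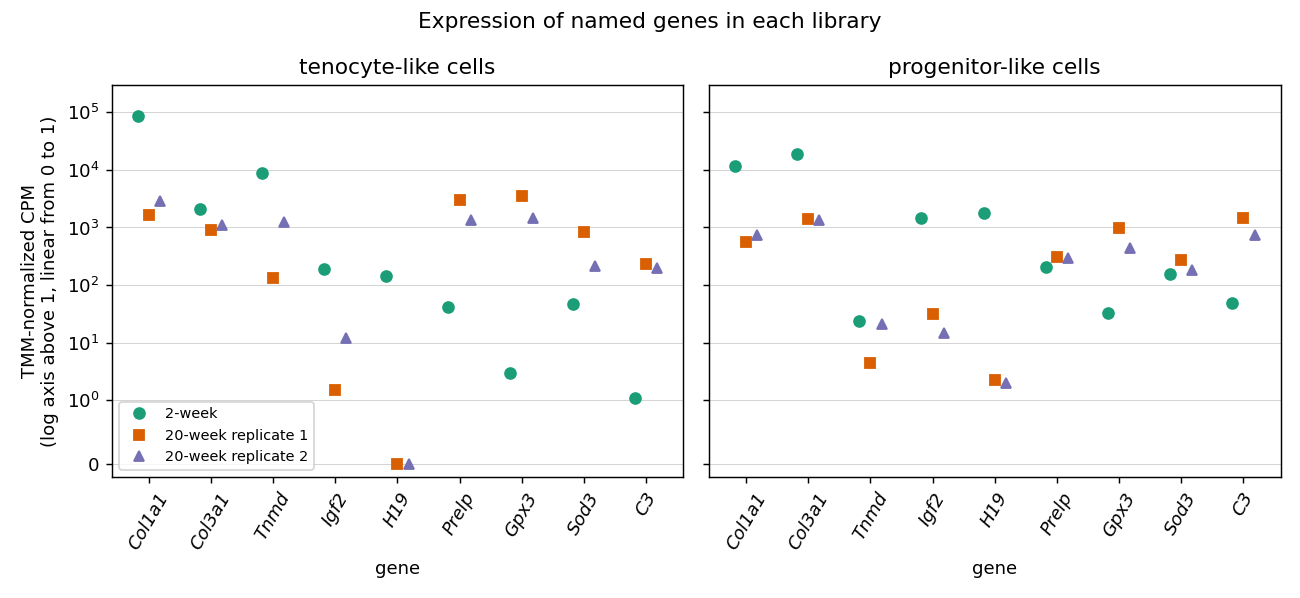
CPM of 9 genes, picked after their values were seen, in tenocyte-like cells (left) and progenitor-like cells (right), on an axis that is linear from 0 to 1 CPM and logarithmic above; each point is 1 library. In both classes Col1a1, Igf2 and H19 lie highest in the 2-week library, and Gpx3 and C3 lie lowest there.

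The comparison within progenitor-like cells addressed the population that the title of the series names. The imprinted noncoding RNA H19 had the lowest p here. It fell from 1794 CPM to 2.22 and 1.96 (log2 -9.78, SE 0.78, adjusted p = 4.6e-06), Igf2 fell from 1471 to 31.0 and 14.8 (log2 -6.15, SE 0.66, adjusted p = 7.6e-05), and Dlk1 went from 1246 UMIs to 0, at least 253-fold lower. Cthrc1 fell from 555 CPM to 2.22 and 1.12 (log2 -8.72, SE 0.74, adjusted p = 5.8e-06). Interstitial collagens were lower too: Col1a1 fell from 11529 CPM to 552 and 741 (log2 -4.15, SE 0.64, adjusted p = 0.00164) and Col3a1 from 19134 to 1410 and 1330 (log2 -3.80, SE 0.65, adjusted p = 0.00295). Comp, a pentameric cartilage and tendon matrix protein, rose from 6.65 CPM to 295 and 273 (log2 5.41, SE 0.72, adjusted p = 5.2e-04), and Gpx3 rose from 32.0 to 993 and 436 (log2 4.47, SE 0.79, adjusted p = 0.00414). The class held 885, 155 and 545 cells with 6510494, 485133 and 3382388 UMIs. Of 11407 genes tested, 145 were higher and 96 lower at 20 weeks, with 1110 at an unadjusted p under 0.05. Nearly all 2-week cells of the class lay in clusters 2 and 12 and nearly all 20-week cells in cluster 1. The count moved with the setting: DESeq2 called 135, of which 112 were also called above, and edgeR called 9 genes higher and 17 lower with the called doublets kept and 69 higher and 59 lower with DESeq2-type scaling. With each library clustered on its own, 310 genes were called, 179 of them the same genes in the same direction. Without a test, 534 genes were at least 2-fold higher and 481 at least 2-fold lower in both 20-week libraries and 181 changed 2-fold in opposite directions, where simulated data gave 495 to 526 unchanged genes the same way in both.

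Other genes with large changes in progenitor-like cells were Inmt, Cxcl14, Hmcn2, Galnt15, Crispld2, Fmo2 and C7 among those higher, and Nrk, Postn and Cpz among those lower. Galnt15 rose from 0.756 CPM to 51.0 and 129 (log2 6.90, SE 0.83), and Fmo2, a flavin monooxygenase, from 4.23 to 68.7 and 240 (log2 5.23, SE 0.82). Inmt, a methyltransferase, had 1 UMI at 2 weeks and 46 and 1230 at 20 weeks, a ratio of 2096 (375 to 82845). Cxcl14, a chemokine, went from 0.756 CPM to 42.1 and 722 (log2 8.95, SE 1.52). Cxcl14 is also a leading gene of cluster 10, which lay outside the class and held 124, 93 and 43 cells of the 3 libraries. Without replicate 1 the log2 change was 9.10 for Cxcl14, 7.61 for Hmcn2 and 5.87 for C7, and without replicate 2 it was 5.02, 4.72 and 2.26. Postn, the matricellular protein periostin, fell from 2011 CPM to 120 and 24.0 (log2 -4.92, SE 0.76, adjusted p = 0.00164), and Nrk and Cpz fell by 5.49 and 4.17 on the log2 scale. By DESeq2 the adjusted p was 0.573 for C7 and 0.184 for Postn. Fmo2 and Hmcn2 are also leading genes of cluster 8, which lay outside the class and held 267, 7 and 4 cells of the 3 libraries. Their rises thus also describe which cells the class took in at each age. At resolution 1.0 a cluster of 8, 25 and 310 cells led by Hmcn2 and Fmo2 lay outside the class, which then held 232 cells of replicate 2. With each library clustered on its own, such a cluster of replicate 2 also lay outside it, and the log2 changes were 5.93 for Hmcn2, 4.28 for Fmo2, 5.52 for Cxcl14 and 4.03 for Crispld2, each still called. Hbb-bs, a haemoglobin chain, fell from 498 CPM to 0 and 8.38 (log2 -6.29, SE 0.71), with an adjusted p of 0.890 by DESeq2. Its 2-week UMIs lay in 37 of 885 cells (4.18%), and those of replicate 2 in 24 of 545 (4.40%). Xist had 0 UMIs at 2 weeks and 231 and 21 at 20 weeks, at least 138-fold higher over the group, with an adjusted p of 0.230 by DESeq2. The 21 UMIs of replicate 2 lay in 5 of 545 cells. Y-linked UMIs were found in 62.4% of 2-week progenitor-like cells, so this change cannot be told apart from the sex of the animals.

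In progenitor-like cells the imprinted growth network shifted down (adjusted p = 9.3e-35; adjusted p = 0.325 with an estimated correlation), with 9 of 16 members lower over all genes and 12 adjusted over the list alone, among them Peg3, Plagl1, Rian and Meg3 with log2 changes of -2.56 to -3.35. Fibrillar collagens and collagen processing shifted down (adjusted p = 2.1e-13; adjusted p = 0.325 with an estimated correlation), with 4 of 31 lower over all genes and 11 adjusted over the list alone. The elastic fibre list shifted down (adjusted p = 0.00555; adjusted p = 0.374 with an estimated correlation), with 2 of 17 lower over all genes, and 4 lower and 1 higher adjusted over the list alone. Fbn2 went from 211 UMIs to 0, at least 42.8-fold lower, and Mfap2 fell by 3.14 on the log2 scale. Complement shifted up (adjusted p = 3.3e-13; adjusted p = 0.325 with an estimated correlation), with 5 of 11 higher over all genes and 7 adjusted over the list alone. C3 rose from 49.7 CPM to 1452 and 727 (log2 4.45, SE 0.79, adjusted p = 0.00422), although C3 also leads cluster 12, which held 2-week cells alone, and C4b rose from 14.2 to 129 and 125 (log2 3.16, SE 0.57). C4b is also a leading gene of cluster 10, which lay outside the class and held 124, 93 and 43 cells of the 3 libraries. The leucine-rich proteoglycan and mature matrix list shifted up (adjusted p = 1.2e-07; adjusted p = 0.325 with an estimated correlation), with 5 of 21 higher over all genes, and 8 higher and 1 lower adjusted over the list alone. Its members Cilp and Prg4, the lubricin of joint surfaces, rose (log2 4.91, SE 0.80 and 4.10, SE 0.74). Cilp is also a leading gene of cluster 8, which lay outside the class and held 267, 7 and 4 cells of the 3 libraries. The tendon lineage list shifted up (adjusted p = 0.00333; adjusted p = 0.374 with an estimated correlation), with Comp and Chad higher and Nrep lower over all 14 measured members, and 7 higher and 2 lower adjusted over the list alone. With each library clustered on its own that list had an adjusted p of 0.710.

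Among the redox genes of progenitor-like cells, Gpx3 was the 1 antioxidant enzyme of 24 that passed over all genes, while 3 were higher and 1 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.899, direction up, median -0.12, mean 0.15). Sod3 stood at 154 CPM at 2 weeks and 268 and 181 at 20 weeks (log2 0.53, SE 0.55, adjusted p = 0.938), and Nfe2l2 at 123, 173 and 171 (adjusted p = 0.947). The NRF2 target list shifted up (adjusted p = 0.00213; adjusted p = 0.374 with an estimated correlation), with Hmox1, the haem oxygenase, higher over all genes (log2 2.58, SE 0.62, adjusted p = 0.0350, 0.184 by DESeq2 and 0.270 with each library clustered on its own) and 2 of 22 higher adjusted over the list alone. Sources of reactive oxygen shifted up (adjusted p = 2.8e-05; adjusted p = 0.325 with an estimated correlation), with Maob higher over all genes (log2 2.82, SE 0.58, adjusted p = 0.0131, and 0.102 by DESeq2) and 4 of 6 higher adjusted over the list alone. Oxidative phosphorylation shifted down (adjusted p = 0.0210; adjusted p = 0.720 with an estimated correlation) with 0 of 38 members called over all genes or over the list alone, at a median of -0.30.

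Inflammatory and stress lists differed in progenitor-like cells as well. The interferon list shifted up (adjusted p = 6.8e-09; adjusted p = 0.325 with an estimated correlation), with no member of 21 called over all genes and 7 higher adjusted over the list alone. Senescence and secretory factors shifted up (adjusted p = 4.0e-04; adjusted p = 0.325 with an estimated correlation), with 3 of 19 higher over all genes, and 7 higher and 1 lower adjusted over the list alone. The 3 were the cytokine Il6, which rose from 2.57 CPM to 39.9 and 83.8 (log2 4.64, SE 0.67, adjusted p = 0.00109), and the chemokines Cxcl1 and Cxcl2 (log2 3.30, SE 0.67 and 5.08, SE 1.13), the last with an adjusted p of 0.527 by DESeq2 and 0.0522 with each library clustered on its own. Cdkn1a stood at 134, 762 and 391 CPM (log2 2.10, SE 0.66, adjusted p = 0.141), and Cdkn2a had no UMI in any library. The dissociation and heat shock list, which holds genes that enzymatic digestion of tissue induces, shifted up (adjusted p = 2.8e-08; adjusted p = 0.325 with an estimated correlation) with no member of 26 called over all genes or over the list alone. The secretory pathway list shifted down (adjusted p = 0.00555; adjusted p = 0.542 with an estimated correlation), with no member of 19 called either way. The cell cycle list shifted down (adjusted p = 1.5e-05; adjusted p = 0.325 with an estimated correlation and 0.799, upward, with sums thinned to the smallest library), with no member of 22 called over all genes and 4 lower adjusted over the list alone. The adipogenic list shifted up (adjusted p = 0.0269; adjusted p = 0.542 with an estimated correlation), where Apoe and Apod rose over all genes and over the list alone (log2 3.72, SE 0.68 and 2.68, SE 0.65, of 7 members). Against random lists the adipogenic list had an adjusted p of 0.239. With each library clustered on its own, the adjusted p was 0.221 for the cell cycle and adipogenic lists and 0.619 for senescence and secretory factors. Progenitor markers shifted down (adjusted p = 0.0400; adjusted p = 0.603 with an estimated correlation, 0.303 with each library clustered on its own and 0.118 with sums thinned to the smallest library), with no member of 15 called, and all 10 markers that named the class are in this list. Cd55, Cd248 and Tppp3 had log2 changes of -0.31 (SE 0.58), -0.47 (SE 0.62) and 0.39 (SE 0.63), none past the test. Matrix degradation (adjusted p = 0.170), with Adamts4 higher over all genes (adjusted p = 0.256 by DESeq2), and fibrocartilage (adjusted p = 0.846, direction up, median 1.78, mean -0.31, 3 genes measured) did not pass. The fibrocartilage list passed, upward, with each library clustered on its own (adjusted p = 0.00382).

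**Figure D2:**
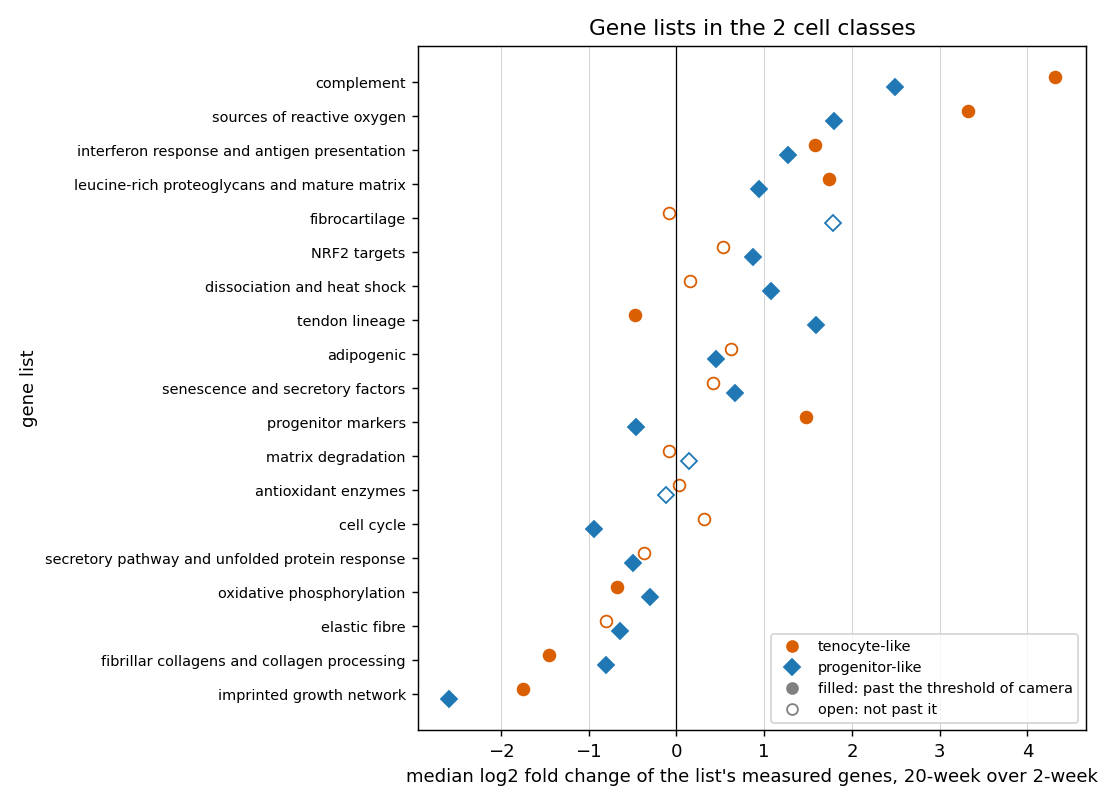
Median log2 fold change, 20-week over 2-week, of the measured genes of 19 gene lists in tenocyte-like cells (circles) and progenitor-like cells (diamonds), with members at 0 in a group set at their bound; filled symbols passed camera's test with a preset correlation of 0.01. Complement has the highest median in both classes (4.32 and 2.50) and the imprinted growth network the lowest (-1.75 and -2.59).

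A test of the interaction between class and age asked where the 2 classes differed in their change with age, with the library as a block. Gpx3 rose in both classes and rose more in tenocyte-like cells, with a difference, progenitor-like minus tenocyte-like, of -5.18 on the log2 scale (SE 0.53, adjusted p = 0.0165). Prelp differed by -5.03 (SE 0.57, adjusted p = 0.0165): it rose in tenocyte-like cells and had a log2 change of 0.52 (adjusted p = 0.945) in progenitor-like cells. Sparcl1, a secreted relative of the matrix protein osteonectin, differed by 4.39 (SE 0.54, adjusted p = 0.0245), with a log2 change of 4.59 in progenitor-like and 0.41 in tenocyte-like cells. Among 11455 genes tested, 7 had a more positive change in progenitor-like and 16 in tenocyte-like cells, with 710 at an unadjusted p under 0.05. DESeq2 called 40, and the other settings run called 87 to 429. Calls within the 2 classes overlapped: of 7853 genes tested in both, 35 were higher in both against 2.03 for independent lists, and 38 were lower in both against 1.00. The 35 include Xist and the tdTomato transgene. Both comparisons draw on the same libraries, and the excess over independent lists was not corrected for this.

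To compare how many cells carried a progenitor marker at equal depth, each cell was thinned to 2000 UMIs, which left 4689, 464 and 892 cells. Ly6a was found in 31.1% of the 2-week cells (exact 95% interval 29.8 to 32.5), 58.8% of 20-week replicate 1 (54.2 to 63.4) and 55.0% of replicate 2 (51.7 to 58.3), and Cd55, a complement inhibitor at the cell surface, in 16.6% (15.6 to 17.7), 27.2% (23.2 to 31.4) and 27.5% (24.6 to 30.5). The 2-week share lay below both 20-week shares for these genes, as did the CPM over all cells, at 635, 1215 and 797 for Ly6a and 194, 306 and 343 for Cd55. Cd248 was found in 23.9%, 26.7% and 27.5%, Tppp3 in 29.5%, 45.7% and 34.1%, and Pdgfra in 26.1%, 27.4% and 51.2%. Without thinning the shares were 36.7%, 57.8% and 60.5% for Ly6a, 27.0%, 29.7% and 38.5% for Cd55, 37.9%, 29.4% and 38.9% for Cd248, 47.7%, 54.5% and 48.5% for Tppp3, and 46.4%, 36.0% and 62.8% for Pdgfra. In mural-like cells, which should lack Ly6a, Cd55 and Pdgfra, the thinned shares over 647, 22 and 18 cells were 0.927%, 4.55% and 0 for Ly6a, 0.309%, 0 and 0 for Cd55 and 0.309%, 0 and 0 for Pdgfra. They were 7.88%, 0 and 5.56% for Cd248, and 29.8%, 22.7% and 9 of 18 cells for Tppp3. At 20 weeks the mural-like shares rest on 22 and 18 cells, too few to set a close bound on the background. At 2 weeks Cd248 was found in 73.4% of progenitor-like and 1.55% of tenocyte-like cells and Tppp3 in 54.3% and 9.12%, so mural-like cells do not serve as a blank for these 2 genes. Before thinning, the cells used had median totals of 6728, 3234.5 and 5666.5 UMIs, and the mural-like cells 7203, 2825.5 and 2591.5.

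Cells with at least 3 UMIs of cell cycle genes, thinned to 2000 UMIs, made up 5.97% of the 2-week library (5.31 to 6.69), 1.29% of 20-week replicate 1 (0.476 to 2.79) and 5.94% of replicate 2 (4.48 to 7.70). Unthinned, the shares were 27.0%, 2.81% and 24.5%. Of the 53 such cells in replicate 2, 31 carried B-lineage RNA, and without B-lineage cells the share was 2.66% (1.68 to 4.0).

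RNA of cell types outside the tendon lineage differed between libraries, although the sort was meant to leave out blood and endothelial cells. Mural cell genes summed to 10028, 2889 and 375 CPM in the 2-week library and in 20-week replicates 1 and 2, and skeletal muscle fibre genes to 487, 12.9 and 5306 CPM. Within tenocyte-like cells mural genes summed to 627, 180 and 158 CPM, Schwann cell genes to 5.04, 116 and 11.9 and muscle fibre genes to 19.5, 12.4 and 129. Within progenitor-like cells mural genes summed to 135, 96.9 and 31.9 CPM and muscle fibre genes to 27.8, 14.4 and 198. Erythroid genes summed to 156, 7.84 and 50.3 CPM, and within progenitor-like cells to 711, 2.06 and 27.8 CPM, beside the fall of Hbb-bs there. Keratinocyte genes summed to 138, 88.5 and 58.3 CPM, and within progenitor-like cells to 445, 233 and 79.8 CPM. Krtdap, a leading gene of cluster 12, gave 395, 202 and 35.2 CPM of the latter. Immune genes summed to 5.59, 8.40 and 190 CPM, most of the last being Cd79a of B cells at 133 CPM, and within progenitor-like cells to 3.38, 6.18 and 23.4 CPM. Endothelial genes summed to 183, 103 and 121 CPM, of which Fabp4, also expressed by mural and fat cells, gave 174, 94.1 and 79.1. Schwann cell genes summed to 87.2, 141 and 57.1 CPM. Sex-linked genes summed to 152, 504 and 188 CPM: Y-linked UMIs were found in 58.0% of 2-week cells, 0 of 606 cells of replicate 1, which allows up to 0.495%, and 50.6% of replicate 2, while Xist was found in 0.0203%, 69.5% and 3.25%. The labels give no sex. Replicate 1 was the one library with Xist UMIs in most cells and no Y-linked UMI.

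On the GRCm38 assembly, the build that mm10 names, Igf2 (ENSMUSG00000048583) lies on chromosome 7 at 142650766 to 142666816 and H19 (ENSMUSG00000000031), a noncoding RNA, at 142575529 to 142578143, both on the reverse strand. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 at 94936224 to 94953042 and Gpx3 (ENSMUSG00000018339) on the same chromosome at 54902453 to 54910377. C3 (ENSMUSG00000024164) lies on chromosome 17 at 57203970 to 57228136.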

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

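The tests on the sex of the animals, on free EGFP RNA, on a mouse transcript read as EGFP and on collagen genes within cluster 10 were chosen after the results were seen, as were the reading of medians beside their SE and clustering each library on its own. The other tests, on free collagen RNA, on collagen genes within cluster 6 and on imprinted genes within cluster 10, were set before their results were seen.

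Gpx3, Prelp, Slurp1 and Ly6c1 had a more positive change with age in tenocyte-like than in progenitor-like cells in the test of the difference itself. The log2 differences, progenitor-like minus tenocyte-like, were -5.18 for Gpx3, -5.03 for Prelp and -4.35 for Ly6c1, each at an adjusted p of 0.0165. Slurp1 had a fitted difference of -12.22 at the same adjusted p, which depends on the prior count because no UMI was found in the 2-week tenocyte-like cells. Hbb-bs, the haemoglobin chain, differed by -7.05 (adjusted p = 0.0165), with a log2 change of -6.29 in progenitor-like cells, where 37 of 885 2-week cells held its UMIs, and 0.17 in tenocyte-like cells. Sparcl1 differed the other way, by 4.39 (adjusted p = 0.0245). Tmem176b differed by 3.70 (adjusted p = 0.0275), with a log2 change of 2.79 in progenitor-like and -0.93 in tenocyte-like cells. Cpxm2 differed by 3.52 (adjusted p = 0.0337), with log2 changes of 2.51 and -1.17. With each library clustered on its own, Tmem176b and Cpxm2 were no longer called (adjusted p = 1 and 0.437), the other genes named here kept their call, and the cause was not tested.

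The feature list held transgene sequences that the comparisons were not built on, and 2 of the 3 gave UMIs although the labels call the animals wild type. EGFP stood at 57.3 CPM over all cells of the 2-week library, 48.2 in 20-week replicate 1 and 10.4 in replicate 2. The tdTomato sequence stood at 30.2, 492 and 253 CPM, and tdTomato-WPRE had no UMI in any library. In the gene tests tdTomato was higher at 20 weeks in tenocyte-like cells (log2 3.72, SE 1.05, adjusted p = 0.0204) and in progenitor-like cells (log2 2.92, SE 0.59, adjusted p = 0.0109).

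Collagen RNA was lower at 20 weeks, with 8 members of the collagen list called in tenocyte-like and 4 in progenitor-like cells. Free collagen RNA in the 2-week droplets was argued against as the whole cause: taking the levels of 119 2-week myogenic-like cells (Col1a1 at 687 CPM) off the 2-week levels moved the members' median log2 ratio from -2.88 to -2.71 in tenocyte-like and from -3.34 to -3.25 in progenitor-like cells. A different mix of clusters in the tenocyte-like class cannot be told apart from age. Cluster 6 was the one such cluster with at least 20 cells of both ages. There replicate 2 over the 2-week library had a median of -1.73 with 8 of 8 members lower, over 74 and 213 cells. This met a bound of -1 set beforehand, but the 8 members were picked because they were called in the class, which holds these cells. Replicate 1 had 6 cells there. Within cluster 10, which no class holds, the 8 members had medians of -1.26 (SE over members 0.33) and -1.09 (SE 0.39) in replicates 1 and 2. Both were short of the -2.88 in the class and within the SE of that bound. A different mix of clusters in the progenitor-like class cannot be told apart from age either, since none of its clusters held at least 20 cells of both ages. Within cluster 10, outside the class, its 4 called members had medians of -2.12 (SE 0.33) in replicate 1 and -1.54 (SE 0.29) in replicate 2. All 4 of 4 were lower in both, against -3.34 in the class, but these members were picked because they were called there. Over all 31 genes of the list the medians in cluster 10 were -0.93 (23 lower) and -0.97 (26 lower), which did not reach -1, against -0.80 in the class. Lower collagen expression with age stays open as an untested biological explanation, because age is confounded with the single 2-week library.

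The imprinted growth network was lower in progenitor-like cells at 20 weeks. Different clusters behind the class cannot be told apart from age, since none of its clusters held at least 20 cells of both ages. Within cluster 10, which no class holds, the list's median log2 ratio over the 2-week library was -2.18 (SE over members 0.75) in replicate 1 and -1.87 (SE 0.73) in replicate 2. There 15 and 14 of 16 genes were lower, over 93 and 43 cells against 124. These medians met a bound of -1 set beforehand, so the list was also lower within a single cluster, but one outside the class. The sex of the animals stays open: replicate 2, whose cells carry Y-linked UMIs like the 2-week cells, had a median of -2.51 in progenitor-like cells with 15 of 16 genes lower, but it is the one 20-week library that carries them. Age itself stays open and untested for the same reason as above.

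EGFP UMIs at 20 weeks were denser in tenocyte-like than in progenitor-like cells. EGFP stood at 116 and 62.1 CPM in tenocyte-like and 2.06 and 1.77 in progenitor-like cells of replicates 1 and 2, a ratio of 56.1 (counting interval 9.80 to 2243) and 35.0 (14.1 to 104), while the 2-week ratio was 1.30 (1.11 to 1.52). Free RNA in the 20-week droplets was argued against by the lower bound of 9.80, since free RNA would give both classes a like level. Reads of a mouse transcript assigned to the EGFP sequence stay open, because the labels call the animals wild type and no library is labelled as carrying the transgene for comparison. Between the ages EGFP was lower in progenitor-like cells (log2 -4.61, SE 0.64, adjusted p = 6.5e-04) and did not pass in tenocyte-like cells (log2 0.49, adjusted p = 0.970), and no biological explanation was tested.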

How the results depend on the processing

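Clustering each library on its own was added after seeing the data; the other alternatives were set beforehand. Of 126 alternative values of the main counts and shares, 58 stayed within their limits and 68 did not. No named gene that was called reversed its direction, though the balance of higher and lower genes turned in some counts given below. Of 666 alternative values of named genes, 485 were kept and 181 changed. DESeq2 kept the side of the threshold for 171 of 222, gained 31 and lost 20. Without replicate 1, 63 of 222 moved by more than the SE of the fitted change, and without replicate 2, 67 did. For each change below the cause was not tested, unless one is given.

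DESeq2 called 191 genes in all cells (115 higher, 76 lower) in place of 16 (2 higher, 14 lower), 138 in tenocyte-like cells in place of 315, 135 in progenitor-like cells in place of 241, and 40 genes that differed between the classes in place of 23. DESeq2-type scaling in edgeR gave 128 in progenitor-like cells and 126 between the classes. Without a filter on low counts edgeR called 658 in all cells (379 higher, 279 lower), 423 in progenitor-like cells and 257 between the classes. With sums thinned to the smallest library it called 0 in all cells (797 at an unadjusted p under 0.05), 188 in tenocyte-like cells and 87 between the classes. Stricter cell filters gave 0 in all cells (955 at an unadjusted p under 0.05) and 663 in tenocyte-like cells (318 higher, 345 lower, against 167 and 148). Keeping the called doublets gave 26 in progenitor-like cells (9 higher, 17 lower, against 145 and 96) and 144 between the classes. Resolution 1.0 gave 674 in tenocyte-like cells and 253 between the classes, z-scoring over all cells gave 661 in tenocyte-like cells, 537 in progenitor-like cells and 429 between the classes, and clustering each library on its own gave 90 between the classes. With an estimated correlation, camera called 0 lists in each of the 3 comparisons, in place of 13, 9 and 16, with 0, 0 and 1 lists at an unadjusted p under 0.05. With 1 residual degree of freedom that alternative could hardly call a list. The imprinted list in progenitor-like cells had a camera p of 4.9e-36 with the preset and 0.0471 with the estimated correlation, which was -0.067. With sums thinned to the smallest library, camera called 13, 8 and 14 lists. In tenocyte-like cells it lost the sources of reactive oxygen and the interferon list (adjusted p = 0.201 and 0.0784) and gained NRF2 targets (0.0148), and in progenitor-like cells it lost the cell cycle list and progenitor markers (0.799 and 0.118). Random lists called 13, 10 and 16, not all the same lists. They lost tendon lineage and elastic fibre in all cells (adjusted p = 0.409 and 0.0897), tendon lineage in tenocyte-like (0.201) and the adipogenic list in progenitor-like cells (0.239). They gained matrix degradation and oxidative phosphorylation in all cells (0.00138 and 0.0219), elastic fibre and NRF2 targets in tenocyte-like (0.0127 and 0.0346) and fibrocartilage in progenitor-like cells (0.0354).

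Counts of genes changed at least 2-fold ranged from 2299 to 2305 in tenocyte-like cells and from 2329 to 2901 in progenitor-like cells without 1 of the 20-week replicates, in place of 1030 and 1015. They are larger by construction, since 1 library has to pass in place of both. Without a filter the tenocyte-like count was 2321, over more genes.

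The progenitor-like share went from 18.0% to 16.7% at 2 weeks, from 25.6% to 21.3% in replicate 1 and from 53.7% to 22.9% in replicate 2 at resolution 1.0. Z-scoring over all cells gave 14.8%, 35.6% and 61.6%, stricter filters 4.77% in replicate 1 and 0.827% in replicate 2, and clustering each library on its own 18.0% and 22.1%. The tenocyte-like share of replicate 2 went from 11.1% to 15.6%, 14.0% and 14.9% under the first 3 of these settings, and that of replicate 1 from 39.8% to 23.6% with each library on its own. With stricter filters an unnamed cluster held 18, 166 and 518 cells of the 3 libraries, so the progenitor-like shares there also describe which clusters took the name.

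Thinning to 1000 UMIs lowers a share of cells with a UMI by construction. For Cd55, Cd248, Tppp3, Ly6a and Pdgfra it gave 11.1%, 15.98%, 19.1%, 25.1% and 16.3% at 2 weeks, 14.4%, 17.8%, 34.8%, 41.9% and 15.2% in replicate 1, and 18.6%, 15.98%, 21.4%, 40.8% and 33.0% in replicate 2. Stricter filters gave 32.5% for Ly6a at 2 weeks, and 51.5% for Tppp3 and 63.5% for Ly6a in replicate 1. The cell cycle share was 3.15%, 0.165% and 3.45% at 1000 UMIs and 13.5%, 6.03% and 15.1% at a minimum of 2 UMIs, which by construction is easier to pass.

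No paired analysis was possible because the 2-week group has 1 library and no label pairs it with a 20-week library. With stricter filters, the tests and the 2-fold count in progenitor-like cells and the test between the classes were not run, since the smallest library held 7 cells of that class. At that setting an unnamed cluster of 18, 166 and 518 cells lay outside the class. Depth limits the smallest sums, 418905 UMIs in tenocyte-like cells of replicate 2 and 485133 in progenitor-like cells of replicate 1. In simulated counts edgeR recovered a 4-fold change in 0% of genes in tenocyte-like and 28% in progenitor-like cells. In all cells, whose smallest sum was 1784768 UMIs, it recovered 3.5%, so recovery did not follow the smallest sum. The 200 simulated genes all changed by the same fold with a common spread, so these shares do not carry over to the real tests.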

Other observations

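Genes that rose with age in both tenocyte-like and progenitor-like cells reached beyond the lists; these genes, and the counts of B-lineage and sex-linked UMIs in single cells, were chosen after their values were seen. Myoc, which encodes the secreted glycoprotein myocilin, went from 14.1 CPM to 4274 and 2547 in tenocyte-like cells (log2 7.91, SE 1.52, adjusted p = 1.2e-04) and from 134 to 3628 and 3253 in progenitor-like cells (log2 4.68, SE 0.80, adjusted p = 0.00323). Serpina3n, a secreted protease inhibitor, rose by log2 changes of 4.49 (SE 0.86) and 2.74 (SE 0.58). The lipid transporter family members Abca8a and Abca8b rose by 6.44 and 3.38 in tenocyte-like and by 3.89 and 3.72 in progenitor-like cells. In tenocyte-like cells these rises, and that of Cygb, the oxygen-binding cytoglobin, lay mostly in replicate 2: Abca8b stood at 5.88 CPM at 2 weeks and 5.97 and 121 at 20 weeks. Smoc2, a matricellular protein, rose by 2.91 and 4.03, and Msx1, a homeobox transcription factor of limb development, by 2.81 and 3.02. Fmo2, Hmcn2, Abca8a, Smoc2 and Cygb are also leading genes of cluster 8, which no class holds and which was made up of 267 cells of the 2-week library, 7 of replicate 1 and 4 of replicate 2. At resolution 1.0 Hmcn2, Smoc2, Abca8a and Abca8b also led an unnamed cluster of 8, 25 and 310 cells of the 3 libraries. With z-scoring over all cells, Myoc was a leading gene of an unnamed cluster of 1247, 0 and 2 cells. With each library clustered on its own, it was one of an unnamed cluster of 956 2-week cells. Its values within the classes thus leave out 2-week cells with its RNA.

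Of the 38 genes lower in both classes, 3 were picked by hand after their values were seen. Ptn, the growth factor pleiotrophin, fell from 1147 CPM to 20.9 and 107 in tenocyte-like cells (log2 -4.18, SE 0.87, adjusted p = 5.4e-04) and from 376 to 15.5 and 45.8 in progenitor-like cells (log2 -3.47, SE 0.57, adjusted p = 0.00238). Sfrp2, a secreted antagonist of Wnt signalling, fell by 3.36 and 3.62 on the log2 scale, and Gpc3, a cell surface heparan sulphate proteoglycan, fell by 2.48 and 2.31. Ptn and Sfrp2 are leading genes of cluster 0, which no class holds and which was made up of 1110, 42 and 18 cells of the 3 libraries.

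B-lineage RNA was found in 66 of the 1014 cells of 20-week replicate 2 (6.51%, exact 95% interval 5.07 to 8.21), all in cluster 13, and in 0 of 4925 and 0 of 606 cells of the other libraries, at a minimum of 3 UMIs per cell. Over all cells of replicate 2, Vpreb3 stood at 214, Igkc at 206 and Cd79a at 133 CPM, although the sort was meant to leave out blood cells. Cluster 18, which no class holds, was made up of 46 cells of replicate 2 alone, led by Ibsp, Cytl1, Clu and Spp1.

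Sex-linked UMIs differed between cells of 20-week replicate 2: 33 cells had Xist without a Y-linked UMI, 513 had Y-linked UMIs without Xist, and 0 had both. Among its tenocyte-like cells the counts were 13 and 40, and among its progenitor-like cells 5 and 326. In replicate 1, 421 cells had Xist and 0 had Y-linked UMIs. In the 2-week library 2857 cells had Y-linked UMIs alone and 1 had both.

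The first 7 bases of the barcodes took 957 distinct values over the 5654 barcodes of the 2-week library, 48 over the 715 of replicate 1 and 673 over the 1169 of replicate 2, where random bases would give 4782, 700 and 1128. The 2-week library shared 2 barcodes with replicate 1 and 3 with replicate 2, and the 20-week libraries shared 0.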
